A study of Homo sapiens with 2 samples.

How the data were processed

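MicroRNA levels were measured in A549 cells, a human lung adenocarcinoma line, with 1-colour Agilent microarrays. Cells had been infected with a lentivirus carrying a transgene or with an empty lentivirus, and total RNA was taken 4 days later. The identity of the transgene is not reported here. The groups were taken from the sample labels, with 1 array for the transgene and 1 array for the vector control. With no replicate in either group, no test across samples was possible, so no p-value is given and every difference compares these 2 arrays.

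The deposited scanner files hold spot values as intensity on a linear scale, written by Agilent Feature Extraction 9.5.1.1 with its microRNA protocol, per the file headers. The same headers record that spatial detrending was on and multiplicative detrending off. The processed signal equalled the background-subtracted signal on the transgene array, within 1 part in 10000 of its size. This was not checked on the vector array. The deposited files also carry flags of other kinds for each spot (control type, outlier, saturation, well above background), set by the same software. The deposited series table gives log2 values made by the authors, with no statement of how they were scaled or centred. Sorted on each array, its values were compared with log2 of the scanner software's total signal per microRNA, with signals under 1 set to 1. The sorted values matched to within 0.001 once a constant was subtracted from log2 of the total signal. The constant was 5.81 on the transgene array and 5.26 on the vector array. Single entries were not matched. The origin of these constants is not given in the sources used here, so the centring stays unknown while scale and direction are settled. The column medians of that table were -5.10 and -4.75. Its entries are numbered and carry no microRNA names, so it served only for counts.

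Each array held 10993 spots, of which 9800 belonged to 1136 probes for 470 human microRNAs. Control spots and spots marked as outliers by the scanner software were left out, which removed 299 spots (3.05%) on the transgene array and 427 spots (4.36%) on the vector array. No spot for a human microRNA was saturated. A probe counted as detected on an array when at least 50% of its usable spots were marked well above background. Log2 processed signals were averaged over the spots of a probe. Each array was then scaled by subtracting its 75th percentile over the 323 probes detected on both arrays, which was 8.53 on the transgene array and 8.15 on the vector array. Probes of a microRNA detected on both arrays were averaged, and the difference is given as transgene minus vector control on the log2 scale.

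The error given with a difference is a standard error (SE) from the spread of spots within a probe. It covers spot noise only, not scaling, RNA preparation or cell culture. The median SE was 0.03 and the largest was 0.44. Of the 132 microRNAs with 2 or more probes in use, 13 had probes of opposite sign, none of them among the microRNAs past 2-fold. The gap between a microRNA's extreme probes had a median of 0.09 and a 90th percentile of 0.31.

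A microRNA detected on 1 array only has a bound in place of a fold. The bright array's mean over its detected probes was set against the higher of the dim array's lowest signal among detected probes (9.68 signal units for the transgene, 8.33 for vector control) and the dim probe's own signal. No fold was given for bounds under 1 or where neither array detected the microRNA.

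Before the data were examined, 21 lists of microRNAs (192 entries, 187 of them on the array) were fixed by family, genomic cluster or cell type. For the 13 lists with at least 3 members detected on both arrays, the median difference was placed among 10000 random lists of the same size, drawn within 5 bins of mean signal. The percentile describes these 2 arrays only. Random lists were drawn from single microRNAs, while members of a family or cluster can be encoded together or bind each other's probes. Such members are not independent, so a percentile can overstate how unusual a list is. The microRNAs named were also set by a rule fixed beforehand. It took miR-375 first, then the 12 largest differences in each direction among microRNAs past 2-fold whose probes had the same sign. Up to 6 microRNAs per direction detected on 1 array with a bound of at least 2-fold came next, then 2 to 4 members per list. Names are those of the array design and can be old. No genome build is recorded with them, so positions are not printed. For the question of genomic neighbours, names were matched to microRNA genes of the RefSeq table for GRCh38.p14, where 451 of the 470 names had a match.

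The alternatives tried were a 75th percentile over all human probes, the median over probes detected on both arrays, no scaling, quantile normalization, normexp background correction with an offset of 50, the median over probes, a floor under all probes, a stricter detection rule, the scanner software's total signal, the series table, a 1.5-fold threshold and scaling on bright control spots. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for normexp.

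The procedure was tested on simulated data with the layout of the real arrays (470 microRNAs, 80 of them changed). All 19 and 16 measured microRNAs with a change of 1.5 or -1.5 came out past 2-fold in the right direction, as did all 20 and 10 with a change of 3.0 or -3.0. None of 86 unchanged microRNAs passed 2-fold, with an SD of 0.05 and a median of -0.09 that came from the estimated shift between arrays (0.50 against a true 0.40). A simulated list of raised microRNAs came out at percentile 95.5, inside the central range from 2.5 to 97.5, so a list with a true shift can be missed. The simulation held spot noise and a common shift, with no variation between cultures and none of single probes between arrays. On the real arrays the 16 bright control features lay between -0.59 and 1.27 after scaling, far wider than the simulated SD. The simulation therefore cannot show how often an unchanged microRNA would pass 2-fold on real arrays.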

Results

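The data were 2 single-colour arrays of A549 cells, 1 from cells with a transgene lentivirus and 1 from cells with an empty lentivirus. Both arrays lay on 1 slide and were read in 1 scan, so no slide or scan date separated the groups, while the place on the slide went with the group. On the transgene array 33.2% of the spots for human microRNAs were well above background, against 31.1% on the vector array. Detected microRNAs numbered 177 on the transgene array and 170 on the vector array. Of all 470 microRNAs, 160 were detected on both arrays, 17 on the transgene array only, 10 on the vector array only and 283 on neither. The transcript of the transgene is not a target of this array, so the labels were not checked against it. The single array per group limits the precision of every value.

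The comparison asked which microRNAs differ in lung adenocarcinoma cells between infection with the transgene lentivirus and with the empty one. The widest separation was that of miR-375, a microRNA of pancreatic islets and other neuroendocrine cells. Its mean signal was 2621 on the transgene array and 1.08 on the vector array, a bound of at least 204-fold higher with the transgene. All 20 of its spots were well above background on the transgene array, with signals from 1161 to 4372, and 0 of 20 were on the vector array, where the brightest reached 4.67. Neural microRNAs miR-9* and miR-9, all 3 measured members of the miR-181 family, and miR-10a and miR-10b from the HOX gene clusters were also higher with the transgene, while miR-30a-5p was lower by 12.6-fold.

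Among the 160 microRNAs detected on both arrays, 26 were higher on the transgene array by at least 2-fold, 18 were lower by at least 2-fold and 116 lay within 2-fold. The median difference was 0.02 and the SD across microRNAs was 1.01. Levels on both arrays correlated at r = 0.89 across microRNAs, which are not independent replicates.

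**Figure D1:**
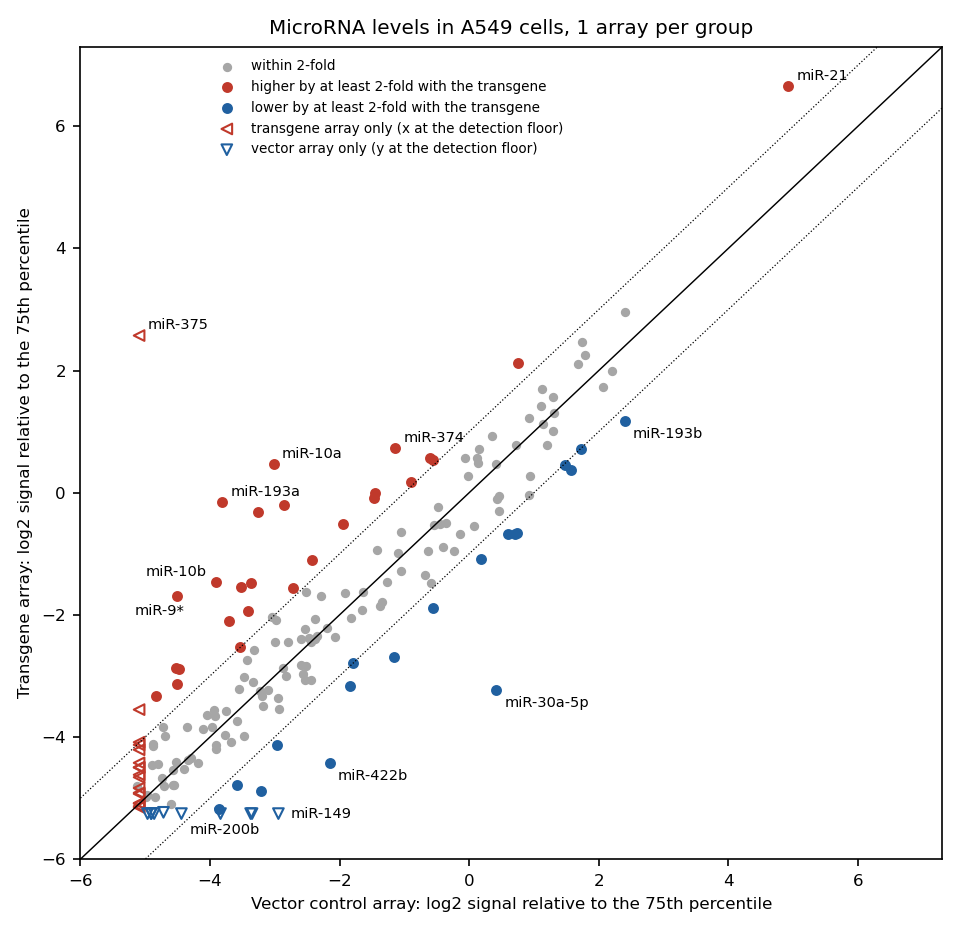
Level of each detected microRNA on the vector control array (x axis) and on the transgene array (y axis), both as log2 signal minus the array's 75th percentile, with 1 array per group. Filled red and blue points are the 26 and 18 microRNAs past 2-fold (dotted lines), grey points the 116 within it, and open triangles the 17 and 10 microRNAs detected on 1 array only, drawn at the other array's detection floor; miR-375 stands at 2.57 on the transgene array.

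The largest difference among microRNAs measured on both arrays was that of miR-193a, 3.66 ± 0.03 on the log2 scale (SE over spots), or 12.7-fold higher with the transgene. It was followed by miR-10a at 3.48 ± 0.03 (11.2-fold), miR-181a at 2.95 ± 0.04 (7.71-fold, from 1 of its 2 probes) and miR-9* at 2.82 ± 0.07 (7.06-fold, 3 of 4 probes). MiR-181b was higher by 2.67 ± 0.03, miR-10b by 2.43 ± 0.03, miR-181d by 1.97 ± 0.02 and miR-9 by 1.89 ± 0.03. The remaining 4 of the 12 were miR-374 at 1.87 ± 0.04, miR-21 at 1.74 ± 0.03, miR-132 at 1.65 ± 0.07 (1 of 2 probes) and miR-335 at 1.62 ± 0.04 (2 of 3 probes). MiR-21, an abundant microRNA of many carcinomas, gave the brightest signal on both arrays, 6.66 above the scaling point with the transgene and 4.93 above it with the vector. Brightness also depends on the probe, and as the brightest on both arrays miR-21 was set to a difference of 0 by quantile normalization.

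On the lower side, miR-30a-5p differed by -3.65 ± 0.03, with its 2 probes at -4.03 and -3.27. MiR-422b followed at -2.27 ± 0.05 (4.83-fold lower with the transgene), miR-30e-3p at -1.67 ± 0.07 (1 of 2 probes) and miR-30c at -1.54 ± 0.03. MiR-27a at -1.41 ± 0.01 and miR-27b at -1.38 ± 0.01 lay together, as did miR-221 at -1.32 ± 0.02 and miR-98 at -1.32 ± 0.04 (1 of 2 probes). The other 4 of the 12 were miR-138 at -1.31 ± 0.04 (its single probe), let-7b at -1.28 ± 0.04, miR-224 at -1.27 ± 0.02 and miR-193b at -1.23 ± 0.02. Thus miR-193a and miR-193b, which belong to 1 family, differed in opposite directions, and they did so with every scaling tried. The miR-138 probe was near the detection limit on the transgene array. Its mean signal there was 10.3, against 9.68 for the lowest detected probe, and the share of its spots well above background was 0.55.

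**Figure D2:**
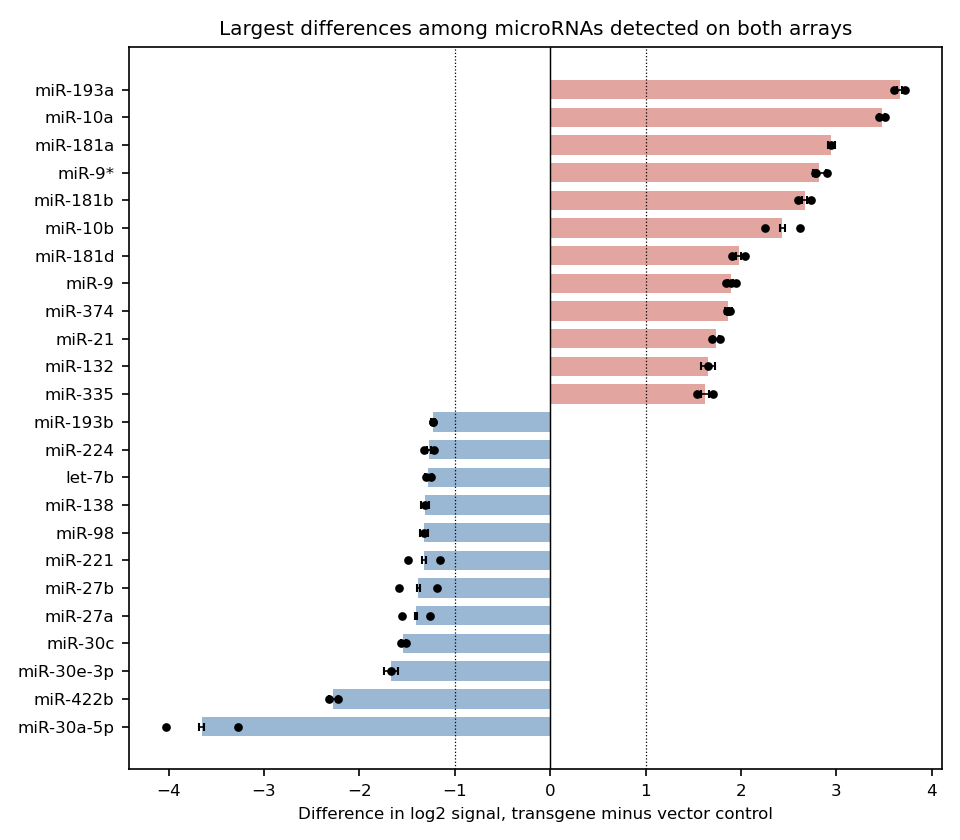
The 12 largest differences in each direction among microRNAs detected on both arrays, as log2 signal with the transgene minus vector control. Bars are means over probes, black points single probes, and error bars the SE over spots, which holds no variation between cultures; the values run from 3.66 for miR-193a to -3.65 for miR-30a-5p.

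Of the 17 microRNAs detected on the transgene array only, 3 had a bound of at least 2-fold. They were miR-375, miR-326 (at least 2.91-fold higher, 1 of 3 probes) and miR-181c (at least 2.01-fold higher). Of the 10 detected on the vector array only, 4 had such a bound. They were miR-149 (at least 4.96-fold lower with the transgene), miR-200b (at least 3.74-fold lower), miR-30a-3p (at least 3.69-fold lower) and miR-200a (at least 2.67-fold lower). The bounds of miR-30a-3p and miR-200a each rest on 1 of 2 probes.

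The scaling sets the balance of higher and lower values, 59.1% of those past 2-fold being higher here. With the median as scaling point every difference moved by -0.37 and 20 were higher against 24 lower (45.5% higher). Without scaling every difference moved by 0.38 and 37 were higher against 6 lower (86.0%). The sign of small differences therefore depended on the scaling. Another 2 settings changed more than the scaling. The series table, with 227 entries compared, gave 32 and 34 (48.5%), and normexp, a background correction, left 10 and 8.

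The list of neural and neuroendocrine microRNAs stood at the high end. Of its 17 members on the array, 8 were detected on both arrays. Of these, 3 (miR-9*, miR-9 and miR-132) were higher by at least 2-fold and 1 (miR-138, near the detection limit with the transgene) was lower. MiR-7, at a level of -2.04 with the transgene and -3.04 with the vector, was just within the threshold, and miR-212, encoded beside miR-132, differed by 0.75. MiR-375 was detected with the transgene only and miR-137 with the vector only, and 7 members, among them the neuronal miR-124a, were detected on neither array. The median difference of the 8 was 0.87, at percentile 98.9 of random lists. Adding miR-375 and miR-137 at their bounds left it at 0.87 by construction, as 1 bound lay above the median and 1 below. The 8 are not independent, as miR-9 and miR-9* are strands of 1 hairpin and miR-132 and miR-212 are neighbours. MiR-128a and miR-128b, also among the 8, belong to 1 family. The median was 0.11 with normexp, at percentile 98.3, and 0.00 with a floor, at percentile 48.4. The floor sets the 7 undetected members to 0 by construction and so says little about the list.

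The miR-181 family, with roles in lymphoid and neural differentiation, had 3 of 4 members measured on both arrays, all higher by at least 2-fold. Its median was 2.67, at percentile 99.2, 2.32 with miR-181c at its bound, and 1.63 with normexp. All 3 detected members of the miR-183 cluster of sensory organs were higher as well, with miR-96 at 1.52, miR-182 at 1.39 and miR-183 at 1.01. MiR-183 was just past the threshold, with 1 of its 2 probes at 0.89. The probe used for miR-96 had a mean signal of 9.96 with the vector, near the lowest detected there (8.33). The cluster's median of 1.39 lay at percentile 97.1, and it was 0.27 with normexp.

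The clusters of miR-23, miR-27 and miR-24 were at the low end. Of their 5 members 4 were lower by at least 2-fold, both miR-27 members, miR-23b at -1.20 and miR-23a just past the threshold. MiR-23a stood at a level of 0.72 with the transgene and 1.72 with the vector. It was within 2-fold, at -0.93, with the scanner software's total signal. MiR-24 was within 2-fold at -0.33, turning positive without scaling. The median of -1.20 lay at percentile 0.48, against random lists whose members are not related as these are. Both members of the miR-221 and miR-222 pair, which target the cell cycle inhibitor p27, were lower, miR-221 at -1.32 and miR-222 at -1.03. With the total signal miR-222 was within 2-fold, at -0.98.

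The list of the miR-30 family was split. It also holds miR-30a-3p and miR-30e-3p, the strands opposite miR-30a-5p and miR-30e-5p in their hairpins. Of 6 members measured on both arrays 3 were lower by at least 2-fold (miR-30a-5p, miR-30e-3p and miR-30c) and none was higher. MiR-30b stood at 0.47, miR-30e-5p at 0.36 and miR-30d at 0.26, the last 2 turning negative with the median as scaling point. The median was -0.64, at percentile 2.94, and it was -1.54 with miR-30a-3p at its bound and -0.30 with normexp. All 9 members of the let-7 family, which represses RAS and HMGA2, were measured. Of these miR-98 and let-7b were lower by at least 2-fold and 7 were within it, including let-7a at -0.01 and let-7c at -0.90, with a median of -0.52 at percentile 6.0.

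Of the microRNAs linked to the tumour suppressor p53, 5 of 6 were measured on both arrays and 2 were higher by at least 2-fold, miR-194 at 1.37 and miR-34b at 1.15. MiR-215 and miR-34a stood at 0.56 each. The median of 0.56 lay at percentile 94.6. In the miR-29 family miR-29c was higher by 1.45, with miR-29b at 0.73 and miR-29a at 0.55, and the median of 0.73 lay at percentile 95.7.

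None of 7 listed members of the miR-200 family and miR-205, microRNAs of epithelial cells, was detected on both arrays. MiR-200a and miR-200b were detected with the vector only, miR-200c with the transgene only at a bound of at least 1.20-fold, and 4 members on neither array. The mean signal of miR-200b on the vector array was 28.7, against 8.33 for the lowest detected probe.

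In 5 further lists no member passed 2-fold, and the sign of the median depended on the scaling. The medians were -0.13 for the miR-17-92 cluster and its paralogs (13 members, percentile 23.0, 0.24 without scaling) and -0.01 for the miR-15 and miR-16 family (5 members, percentile 38.3, 0.37 without scaling). The clusters that hold miR-99a, miR-100 and miR-125b had -0.18 (5 members, percentile 31.4, 0.20 without scaling). The joint list of the miR-130 and miR-148 families with their relatives had 0.27 (6 members, percentile 79.96, -0.10 with median scaling). The imprinted 14q32 cluster had 0.21 over 6 of its 49 members on the array (percentile 81.6, -0.15 with median scaling), and 41 were detected on neither array.

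**Figure D3:**
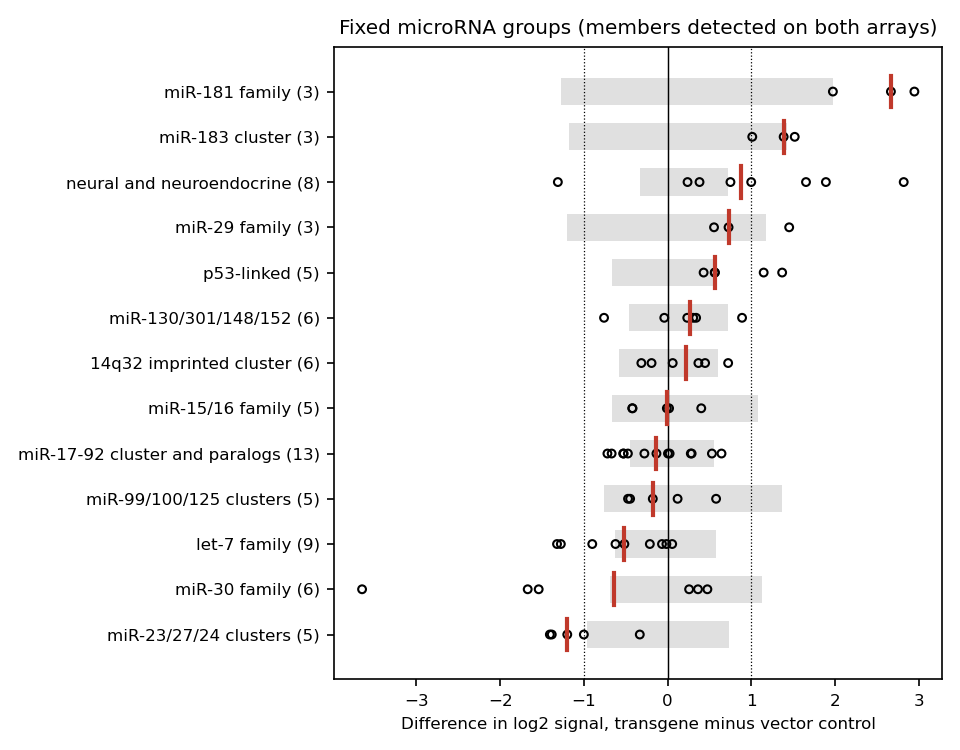
Differences in log2 signal (transgene minus vector control, x axis) for the 13 fixed lists with at least 3 members detected on both arrays, the number of members in brackets. Open circles are members, red bars list medians and grey bands the central range of medians of 10000 random lists; the medians of the miR-181 (2.67), neural (0.87) and miR-23/27/24 (-1.20) lists lie outside their bands, and with the median as scaling point or no scaling the sign turns for the lists named after miR-17-92, miR-15, miR-99, miR-130 and 14q32.

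Markers of other cell types were mostly undetected. None of 6 muscle microRNAs and none of 12 from the embryonic stem cell clusters was detected on either array by the rule on spots used here, while the scanner software's total signal per microRNA counted miR-133a of muscle as detected on both. Of 7 blood cell microRNAs only miR-223 was detected, at -0.15, and of 3 endothelial and liver microRNAs only miR-126, at 0.00. The list of mesenchymal and stromal microRNAs had 1 of 7 members detected, miR-10b, and the other 6, including miR-143 and miR-145, were on neither array. Among 6 microRNAs of the inflammatory response only miR-21 was detected, while miR-146a and miR-155 were not.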

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

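The tests of a scaling constant and of a local defect were chosen after the results were seen, and those of dim spots and of a brighter array were chosen before. A control spot type outside the microRNA measurement drew attention because its difference passed 2-fold. After scaling, control feature Ctrl_00011163 was higher on the transgene array by 1.27 on the log2 scale, with median signals of 7699 and 2443 over 20 spots per array. Of the 16 bright control features it was the 1 past 2-fold, and the other 15 lay between -0.59 and 0.51. The files give no description of what it binds, and no explanation was tested.

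The first pattern weighed was the set of 44 microRNAs past 2-fold. For a single wrong scaling constant, the smallest count that any constant from -2 to 2 left past 2-fold was 41. With a median difference of 0.02 and an SD of 1.01, this followed from the spread of the values. It covers only the number past 2-fold, since which microRNAs passed, and on which side, did change with the scaling. Noise of dim spots is argued against for the 26 of the 44 that were among the 80 brighter microRNAs, while 18 were among the 80 dimmer. The split cannot weigh the dimmer ones fairly. A dim microRNA with a large difference can fall under detection on 1 array and leave the set. Differences between cultures, RNA preparations or places on the slide have 1 array per group to show them and stay open beside an effect of the transgene, which may account for part of the set but was not tested.

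The second pattern was miR-375, detected with the transgene only. On the transgene array 100% of its usable spots were brighter than its brightest spot on the vector array, which repeats the observation that raised the question. A local defect of the array is argued against by the spread of these spots, which spanned 169 of 192 spot lines and 76 of 82 columns. Its 2 probes had mean signals of 4041 and 1202 with the transgene. A response to the transgene could account for this, as a hypothesis, but a difference between the cultures other than the transgene was not tested and cannot be excluded with 1 array each.

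The third pattern was the larger number of microRNAs detected with the transgene only (17) than with the vector only (10). When the transgene signals were lowered by the shift between arrays and 1 threshold of 9.97 signal units was used on both, the numbers were 12 and 11. The brighter transgene array may account for most of the imbalance, which nearly vanished at equal brightness and threshold. The count with the transgene stayed above the other by a margin too small to show a true difference in the number of expressed microRNAs. These explanations cannot be told apart on these counts.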

How the results depend on the processing

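Scaling on bright control spots was chosen after seeing the data, and the other alternatives were fixed before. Of the 44 microRNAs past 2-fold, 44 stayed past it on the same side with a 75th percentile over all human probes and with the median over probes, 43 with scaling on control spots, 42 with a floor, 41 with the scanner software's total signal, 41 of 42 still measured with the stricter detection rule, 40 with quantile normalization, 38 with median scaling, 32 without scaling and 18 with normexp. None had the opposite sign in these settings, and miR-21, the brightest signal on both arrays, was at 0 under quantile normalization by construction. Without scaling, 6 microRNAs were lower. Normexp left 18 past 2-fold, 10 higher and 8 lower, and its offset of 50 shrinks the differences of dim signals by construction. With a floor, 5 list medians lay outside the central range of random lists, against 3. The neural list was no longer outside, at percentile 48.4, since its 7 members detected on neither array stand at a difference of 0 there by construction, while the miR-181 and miR-23/27/24 lists stayed outside and the let-7, miR-30 and miR-183 lists joined them. The miR-30 list was also outside with the stricter detection rule, at percentile 1.59. The series table, with its own constants and more microRNAs above its floor, gave 34 lower, 27 above the floor with the transgene only and 17 with the vector only. At 1.5-fold the numbers were 38 higher and 27 lower. The miR-183 cluster had too few members for a value under the stricter detection rule. No paired analysis was possible because each group has 1 sample. Signal over background set the limit for the 283 microRNAs detected on neither array, whose differences are unknown.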

Other observations

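The microRNAs in this paragraph were chosen after their values were seen. MiR-196a, which like miR-10a and miR-10b is encoded in the HOX clusters, was higher on the transgene array by 1.59 on the log2 scale. Both members of the miR-26 family were higher, miR-26a by 2.26-fold and miR-26b by 2.14-fold. MiR-28 was higher by 1.48 and miR-345 by 1.38.

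Both strands of 8 hairpins, paired by their names in the array design, were measured on both arrays. Gaps between strands ran from 0.04 to 2.03, with 2 of them at 1 or more, and 5 pairs had strands of opposite sign. The examples given were chosen after their values were seen. MiR-9 and miR-9* were both higher with the transgene, by 1.89 and 2.82. MiR-191 was higher by 1.43 ± 0.02, while its partner strand miR-191* stood at -0.23 ± 0.04. MiR-30e-5p stood at 0.36 ± 0.03 and miR-30e-3p at -1.67 ± 0.07. Without scaling miR-191* turned positive, and with the median as scaling point miR-30e-5p turned negative, but the distance within each pair does not depend on a scaling constant. Probes of related family members can also bind each other's targets, which these files do not separate.

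The test of genomic neighbours was chosen after the results were seen. The hypothesis was that microRNAs made from a shared primary transcript may differ alike. Among 47 pairs from different families with genes within 10 kb, the median gap between differences was 0.43, at percentile 0.75 of 10000 reassignments of the values, whose median gap was 0.82. Without the 2 groups with the most pairs (14 pairs around miR-188 and miR-532, and 13 pairs linking miR-17 to miR-106a), 20 pairs were left with a median gap of 0.70, at percentile 28.8, so the small gap rests on those groups. Agreement in sign went the other way. It held for 30 of all 47 pairs, a number reached by 5.58% of reassignments, and for 17 of those 20 pairs, reached by 0.30%. The measures of likeness disagree, pairs of 1 cluster are not independent, and signs of small differences depend on the scaling, so the hypothesis stays open.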
